A study of Rattus norvegicus with 33 samples.

How the data were processed

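Small RNA sequencing of rat plasma was analysed from 6 toxicant models of liver injury. Per the labels, male Sprague-Dawley rats, 5 per group, received acetaminophen (APAP) or thioacetamide (TAA) as hepatocellular models, α-naphthylisothiocyanate (ANIT) or 4,4'-methylenedianiline (MDA) as cholestasis models, or carbon tetrachloride (CCl4) or dexamethasone (DEX) as steatosis models. APAP (1500 mg/kg) and TAA (100 mg/kg) were sampled at 3, 6, 12 and 24 h, and ANIT (150 mg/kg) and MDA (250 mg/kg) at 3, 6, 12, 24 and 48 h. CCl4 (300 mg/kg, once daily) was sampled at Day 1, 3 and 5 and DEX (15 mg/kg, once daily) at Day 1, 2 and 3. ANIT, CCl4 and DEX were given in corn oil and the other compounds in carboxymethylcellulose. Plasma was EDTA blood from the descending aorta, and libraries were sequenced on a MiSeq. Each model had its vehicle group, with 1 group shared by CCl4 and DEX. The 33 labelled samples correspond to 29 distinct columns of the tables, each called a library here, because 4 ANIT groups with 2 labelled samples have 1 column.

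The deposited tables give a read count per mature miRNA and library, and beside it a normalized signal that the authors made by dividing each count by a DESeq size factor (DESeq 1.28.0 per the submitters' processing notes). The tool that counted the reads, the miRNA release and the genome build are not given in the sources used here, so miRNAs are named as in the tables and no coordinates are given. Per table, counts cover 326 to 388 miRNAs and the normalized signal 116 to 169. Of 4113 normalized values, 17.2% differed from the count and its factor by more than 0.5 read, so the counts were used throughout. The vehicle columns of the CCl4 and DEX tables have the same total of 225741 reads and differ in 36 miRNAs by at most 4 reads. They were counted as 1 library, with the CCl4 table's values.

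No group has replicates in the tables. The ANIT groups with 2 labelled samples are vehicle, 12, 24 and 48 h, and it is not stated whether their column is a sum. Whether a library is 1 rat or a pool of 5 is not given in the sources used here either. The replicated ANIT tests that had been planned, including the tests of miRNA lists within ANIT, were therefore not possible, and ANIT was treated like the other 5 models, a choice made after the tables were seen.

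Library totals ran from 14176 (MDA vehicle) to 383330 miRNA reads (TAA 24 h). A count of 0 was read as up to 3 reads, a share of 0.000783% to 0.0212% depending on the library. Shares have exact Clopper-Pearson 95% intervals, and ratios to the vehicle library have the exact 95% interval of the same binomial. These intervals cover counting error only, and not differences between rats, library preparation or PCR copies. For miRNAs at 0 reads in 1 of both libraries, a bound of at least N-fold was computed with 3 reads in place of 0. Log2 ratios used a pseudocount of 0.5 read. Libraries were scaled by TMM within each model (edgeR 4.0.16, R 4.3.3). No spike-in was used, so neither TMM nor total counts gives absolute concentrations. Total counts, with no composition scaling, put ratios lower than TMM did, by a log2 shift of 0.00 (ANIT 3 h) to 2.40 (APAP 12 h).

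Within a model, a miRNA was measured when at least 1 library held 20 reads. It was called higher or lower by a rule of size, which needs a ratio of at least 2 or at most 0.5 and a 95% counting interval that excludes 1. The rule carries no p-value. As yardsticks added after the tables were seen, the rule was applied to the 10 pairs of the 5 vehicle libraries, and each treated library was set against each of the 5 vehicle libraries. The last comparison changes 2 choices, as it needs the call in the same direction against all 5 and scales by 1 TMM over all libraries. The own vehicle with 1 TMM over all libraries was therefore run as well, which moved log2 ratios by −0.50 (CCl4 Day 5) to 0.81 (MDA 12 h). On simulated data for MDA 24 h, 0.947% of unchanged miRNAs passed the rule and 92.2% of those changed 4-fold. The counting intervals covered the simulated ratio in 95.8% to 96.5% of draws, so these rates leave out spread between libraries. Between pairs of vehicle libraries 3.97% to 28.6% of miRNAs passed.

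Across models, 11 libraries were fitted together, the 24 h or Day 1 library and the vehicle library of each model, with the vehicle set as a block. The fit used edgeR's quasi-likelihood test on the 134 miRNAs with at least 10 reads in at least 4 libraries, of 264 miRNAs listed in all 6 tables. Here the models are the replicates. Results are the change against vehicle across 6 models, the change in each injury type (2 models per type) and the 3 differences between types. The SE given with a log2 change is its absolute value divided by the square root of the test's F statistic. It is approximate, above all for miRNAs with 0 reads in a library. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Where a count is given as adjusted over the list alone, the adjustment ran within that list. It has no correction over the lists or the results, so such counts are weaker than those over all tested. Spread between models was wide, with a biological coefficient of variation of 64.6% in the 6-model fit and 44.2% in the fit by type. The fit by type has 3 residual degrees of freedom per miRNA, and edgeR found no difference in spread between miRNAs (an infinite prior), so the test had 402 degrees of freedom, against 12.2 in the 6-model fit. Its small p-values therefore treat 1 shared spread as nearly known. The degrees of freedom were 16.8 at the last sampling time, 13.5 without the TAA vehicle library and 6.86 without CCl4. Each type is 2 compounds, so injury type cannot be separated from compound. The fits were tested on simulated data, 20 sets with 40 changed miRNAs. Changes of 8-fold were recovered at 87.3% across 6 models, 70.0% for hepatocellular, 74.2% for cholestasis and 51.9% for steatosis against vehicle. For the differences between types recovery of 8-fold changes was 26.5% (hepatocellular minus cholestasis), 14.6% (hepatocellular minus steatosis) and 19.6% (cholestasis minus steatosis).

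The 15 miRNA lists, the rule of size, the fits, the alternatives not described as added, and the choice of named miRNAs were fixed before the data were examined. The lists cover liver-enriched, biliary and other epithelial, erythroid, platelet and endothelial, leukocyte, muscle, mesenchymal and stellate, pancreas and gut, brain, and lipid, stress and damage miRNAs, with the let-7, miR-17/92, miR-30, and miR-29 and miR-101 families and the Dlk1-Dio3 cluster. Each list with at least 3 measured members was compared, by its median log2 ratio, with 10000 random lists of the same size drawn from the measured miRNAs of the same library. The share of random lists with a lower median is given as the percentile, which is not a p-value. Named miRNAs are the first 3 measured members of each list (any member for liver, erythroid, leukocyte and muscle), up to 8 per direction and model that passed the rule in at least 2 neighbouring time points, up to 10 per direction and joint result by p, the 3 smallest p where fewer than 3 passed, and the 5 most abundant miRNAs of vehicle plasma by pooled reads. Other miRNAs were chosen after their values were seen and are named as such.

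Alternatives were DESeq2's size factors, total counts, no count filter, DESeq2 1.42.0 as the test, the last sampling time of each model, each model left out, the authors' normalized signal, and a minimum of 50 reads. With a model left out its type rests on 1 treated library, assumed to vary like the other models. Added later were the DEX table's vehicle counts and, since the TAA vehicle library stood apart in the pairs of vehicles, a fit without it in which TAA at 24 h is set against the APAP vehicle, so that both hepatocellular models share 1 vehicle. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the rest. Reads of near-identical mature miRNAs, such as those of let-7, miR-30, miR-1 or miR-200, cannot be assigned with certainty from these tables.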

Results

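Plasma of vehicle-treated rats was dominated by miR-148a-3p, a miRNA made in liver and many other tissues, at 34.1% ± 2.97 of miRNA reads (SD, n = 5 vehicle libraries, range 29.7% to 37.5%). By reads pooled over the vehicle libraries it was followed by miR-140-3p (10.7% ± 3.52), let-7i-5p (5.80% ± 2.08), the red cell miRNA miR-486 (4.75% ± 1.39) and let-7f-5p (3.16% ± 1.63), and by mean share let-7g-5p (4.21%), miR-26a-5p (3.43%), miR-143-3p (3.415%) and miR-215 (3.18%) were also above let-7f-5p. The hepatocyte miRNA miR-122-5p made up 2.15% ± 1.14 of reads, from 0.647% in the shared CCl4 and DEX vehicle to 3.34% in the MDA vehicle. Libraries held between 165 (MDA vehicle) and 319 detected miRNAs (CCl4 and DEX vehicle). Each time point is a single library, so the values per model have no replicate error.

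miR-122-5p was higher than in the model's own vehicle library in 24 of 24 treated libraries. With 1 TMM over all libraries it was higher in all 24 also against each of the 5 vehicle libraries. By share of reads, ANIT at 3 h (4.90%) and CCl4 at Day 1 (4.85%) were less than 2-fold above the MDA vehicle (3.34%). In APAP its share was 2.70% in vehicle, 19.5% at 3 h, 65.5% at 12 h (95% interval 65.3% to 65.6%) and 17.1% at 24 h. TAA reached 54.7% at 12 h from 2.80%, ANIT 49.96% at 48 h from 1.278%, and MDA 58.4% at 24 h from 3.34%. In the steatosis models the highest shares were 23.3% in CCl4 (Day 3) and 11.6% in DEX (Day 3). miR-192-5p, which is shared by liver and intestine, came to its highest shares later in the hepatocellular models, 23.7% at 24 h in APAP and 25.8% at 24 h in TAA. Its highest share was 9.05% in ANIT (48 h) and 6.27% in CCl4 (Day 5).

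**Figure D1:**
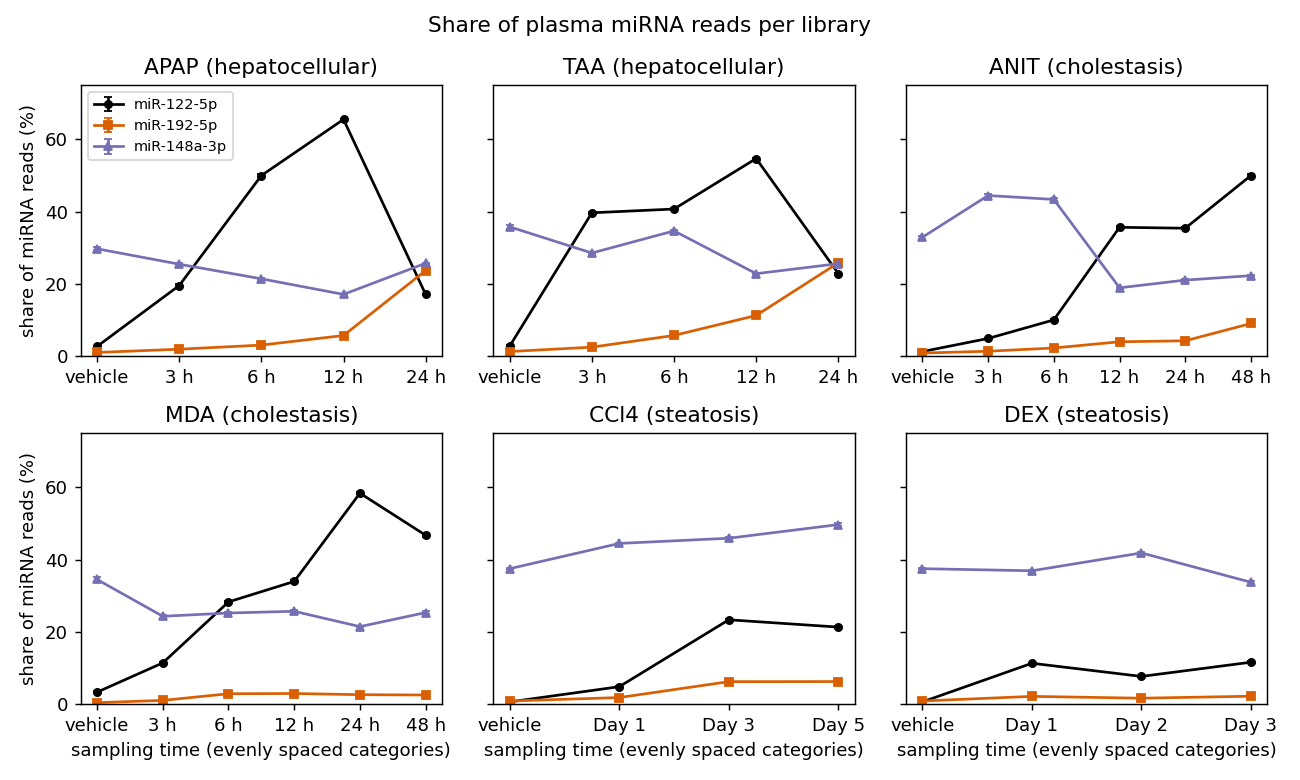
Share of miRNA reads (%) of miR-122-5p, miR-192-5p and miR-148a-3p by sampling time, 1 panel per model, 1 library per point, with exact 95% counting intervals as error bars, most of them smaller than the symbols. In APAP and TAA miR-122-5p is highest at 12 h (65.5% and 54.7%), while miR-192-5p is highest at 24 h (23.7% and 25.8%).

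In the APAP model miR-122-5p was 8.23-fold higher in the 3 h library and 128-fold higher in the 12 h library (95% interval 121 to 135), with 18.2-fold at 24 h. miR-192-5p was 66.1-fold higher at 24 h and miR-101b-3p 70.3-fold (48.6 to 106), and the epithelial miRNA miR-200a-3p was 18.8-fold higher at 12 h (11.9 to 31.6). miR-22-3p was 125-fold higher at 24 h (101 to 155). The lymphocyte miRNA miR-150-5p was 33.9-fold lower at 24 h (20.8 to 58.8), let-7a-5p 32.0-fold (19.1 to 57.9), and the red cell miRNA miR-486 6.49-fold. The muscle miRNAs miR-1-3p (12.6-fold, 9.11 to 18.0) and miR-206-3p (9.86-fold) were higher at 3 h and, at 24 h, 8.63-fold and 20.4-fold lower, while miR-378a-3p of the same list was 23.0-fold higher then. Of 130 measured miRNAs, 21 passed the rule as higher and 9 as lower at 3 h, 20 and 12 at 6 h, 31 and 29 at 12 h, and 54 and 42 at 24 h. With total counts these were 15 and 13, 6 and 66, 7 and 91, and 24 and 69. With 1 TMM over all libraries the balance turned at 3 h (12 and 17) and 12 h (26 and 32). The liver-enriched list had a median log2 ratio of 4.52 at 24 h (2.99 with total counts, percentile 99.9 of random lists), with 9 of 9 members higher. Members at 0 reads in vehicle, miR-122-3p and miR-192-3p among them, were at least 17.7-fold and 7.16-fold higher at 24 h, and with such members at the floor the median was 3.18. Such members reached the read minimum only through treated libraries, which favours higher calls among them.

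In the TAA model miR-122-5p was 29.6-fold higher in the 3 h library and 90.9-fold in the 12 h library (85.2 to 97.0). At 24 h miR-101b-3p was 228-fold higher (144 to 385), miR-192-5p 70.5-fold (64.1 to 77.7) and miR-194-5p, transcribed together with miR-192, 49.5-fold (30.4 to 86.8). miR-3559-5p, with 1 read in vehicle, was 306-fold higher with an interval from 54.9 to 12120. Several miRNAs of blood cells were lower at 24 h, miR-150-5p 55.6-fold (29.5 to 118), the myeloid miR-223-3p 27.6-fold (10.9 to 89.5) and miR-486 27.0-fold (23.1 to 31.6), and miR-451-5p was lower at each time, 4.60-fold at 24 h. The muscle miRNA miR-206-3p was 64.7-fold lower at 24 h (21.1 to 322), and miR-378a-3p of the same list 15.1-fold higher. The TAA vehicle held the highest miR-206-3p value of the 5 vehicle libraries. With the libraries of the joint fit scaled together, that value was 1063, against 209.4 to 314.5 in the other vehicle libraries and 23.53 in TAA at 24 h. The size of this fall therefore depends on the vehicle library used, while its direction does not. Of 123 measured miRNAs, 14 were higher and 13 lower at 3 h, 19 and 10 at 6 h, 31 and 40 at 12 h, and 54 and 44 at 24 h, against 1 and 56, 5 and 71, 5 and 81, and 22 and 66 with total counts. With 1 TMM over all libraries there were 10 and 17 at 3 h and 38 and 33 at 12 h. At 24 h the median of the liver-enriched list was 4.55 (2.73 with total counts, 3.91 with members at 0 reads at the floor), at percentile 100.0. The leukocyte list was at percentile 1.6 at 24 h, with 6 of 7 members lower and a median of −3.53.

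In the ANIT model miR-122-5p was 3.85-fold higher in the 3 h library, 36.7-fold at 12 h and 111-fold at 48 h (103 to 121). miR-200a-3p, abundant in bile duct and other epithelia, was 15.3-fold higher at 12 h, 64.6-fold at 24 h (35.0 to 135) and 6.77-fold at 48 h, and miR-200b-3p was 19.4-fold higher at 24 h (8.20 to 60.4). miR-192-5p was 29.8-fold higher at 48 h. miR-93-5p, of the miR-17 family, was lower at each time, 27.1-fold at 6 h and 16.6-fold at 24 h (10.7 to 27.0), and miR-98-5p, at 0 reads in the 24 h library, was at least 33.8-fold lower there. The values of miR-93-5p ranged 5.52-fold between vehicle libraries, so the sizes of its falls depend on the vehicle library used. Against each of the 5 vehicle libraries, miR-93-5p was lower in 13 of 19 treated libraries of all models. Of 118 measured miRNAs, 7 were higher and 23 lower at 3 h, 26 and 28 at 6 h, 23 and 21 at 12 h, 31 and 29 at 24 h, and 26 and 31 at 48 h. With total counts these were 7 and 23, 14 and 34, 13 and 39, 20 and 41, and 9 and 78, and at 3 h 15 and 13 with the authors' signal and 11 and 14 with 1 TMM over all libraries. The biliary and epithelial list had medians of 3.02 at 12 h and 4.14 at 24 h (2.63 and 3.72 with total counts), both at percentile 100.0, with 4 members higher each time and 1 lower at 24 h. The erythroid list lay at percentile 0.4 at 24 h and 32.5 at 48 h, where miR-451-5p was level with vehicle (1.04-fold, 0.813 to 1.32).

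In the MDA model, whose vehicle library is the shallowest, miR-122-5p was 3.57-fold higher in the 3 h library and 42.4-fold at 24 h (38.7 to 46.5). miR-200a-3p was 37.5-fold higher at 3 h, 25.2-fold at 6 h and 18.7-fold at 12 h. With 3 reads in vehicle, the 3 h interval runs from 12.7 to 183, and the ratios of 2.75 at 24 h (0.8795 to 13.9) and 3.23 at 48 h (0.971 to 16.9) did not pass the rule, though both passed with the authors' signal. The smooth muscle miRNA miR-143-3p took 25.5% of reads at 3 h, more than any other miRNA, and was 2.77-fold higher there (2.61 to 2.94). The red cell miRNA miR-451-5p was 8.80-fold lower at 6 h (5.26 to 15.1) and 1.02-fold of vehicle at 48 h, and miR-16-5p was lower at each time, 10.7-fold at 24 h (4.82 to 25.4). Of 95 measured miRNAs, 16 were higher and 26 lower at 3 h, 18 and 28 at 6 h, 19 and 26 at 12 h, 18 and 32 at 24 h, and 22 and 28 at 48 h. With total counts these were 16 and 28, 8 and 36, 11 and 38, 5 and 56, and 11 and 45, and with the authors' signal 25 and 18 at 24 h and 31 and 16 at 48 h. Scaling by 1 TMM over all libraries turned the balance at every time, to 24 and 16, 32 and 14, 33 and 16, 28 and 16, and 28 and 21. The epithelial list was at percentile 99.8 at 3, 6 and 12 h, with a median of 4.31 at 3 h (4.25 with total counts, 3.74 with members at 0 reads at the floor). The mesenchymal and stellate list was at 98.4 at 3 h, with 4 of 5 members higher under both scalings.

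In the CCl4 model miR-122-5p was 8.92-fold higher in the Day 1 library, 89.5-fold at Day 3 and 90.8-fold at Day 5 (86.1 to 95.8). miR-192-5p was 19.3-fold higher at Day 5, miR-194-5p 10.8-fold, miR-182 10.8-fold (8.66 to 13.6) and miR-22-3p 9.06-fold. miR-148a-3p, the most abundant plasma miRNA, was 3.65-fold higher at Day 5 (3.61 to 3.69), but 1.325-fold with total counts, which did not pass. Several muscle miRNAs were lower at each time, miR-1b 19.7-fold and miR-1-3p 4.89-fold at Day 3 (3.33 to 7.46) and miR-206-3p 4.08-fold at Day 1 (2.39 to 7.42), and that list lay at percentile 0.5 at Day 1, while its member miR-378a-3p was 7.77-fold higher at Day 3. The shared CCl4 and DEX vehicle held the highest miR-1b value of the 5 vehicle libraries. Between vehicle libraries, values ranged 5.06-fold for miR-1b, 6.27-fold for miR-1-3p and 5.42-fold for miR-206-3p, so these sizes depend on the vehicle used. Against each of the 5 vehicle libraries, miR-1b was lower in 0 of 19 treated libraries of all models. miR-1-3p was lower in 5 of 24 and miR-206-3p in 2 of 19. Of 132 measured miRNAs, 8 were higher and 12 lower at Day 1, 24 and 25 at Day 3, and 24 and 22 at Day 5, against 5 and 18, 12 and 80, and 10 and 80 with total counts, and 5 and 17, 19 and 42, and 16 and 38 with 1 TMM over all libraries. At Day 5 the liver-enriched list had a median of 3.43 (1.97 with total counts) and percentile 100.0.

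In the DEX model miR-122-5p was 17.9-fold higher in the Day 1 library, 15.4-fold at Day 2 and 19.7-fold at Day 3 (18.6 to 20.8), while miR-192-5p was 2.72-fold higher at Day 3 (2.54 to 2.91). miR-375-3p, of islets and neuroendocrine cells, was 4.35-fold higher at Day 1 (3.26 to 5.84), miR-27a-5p 9.09-fold at Day 3 (5.24 to 16.4) and miR-223-5p 6.37-fold at Day 3 (4.48 to 9.12). The immune cell miRNAs miR-150-5p (4.23-fold at Day 2, 3.65 to 4.93) and miR-155-5p (8.89-fold at Day 3) were lower. Against each of the 5 vehicle libraries, neither the rise of miR-27a-5p nor the fall of miR-155-5p was called in any treated library. Their values ranged 8.07-fold and 8.94-fold between vehicle libraries. miR-455-3p was 8.06-fold lower at Day 3 (3.63 to 22.3), and miR-93-5p 5.29-fold lower at Day 1. Of 131 measured miRNAs, 20 were higher and 21 lower at Day 1, 23 and 16 at Day 2, and 26 and 20 at Day 3, against 18 and 24, 16 and 29, and 22 and 24 with total counts, and 14 and 42, 16 and 29, and 19 and 32 with 1 TMM over all libraries. The liver-enriched list lay at percentiles 93.0, 89.8 and 81.4, and the miR-17/92 list at 1.2 at Day 1 with 4 of 4 members lower.

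**Figure D2:**
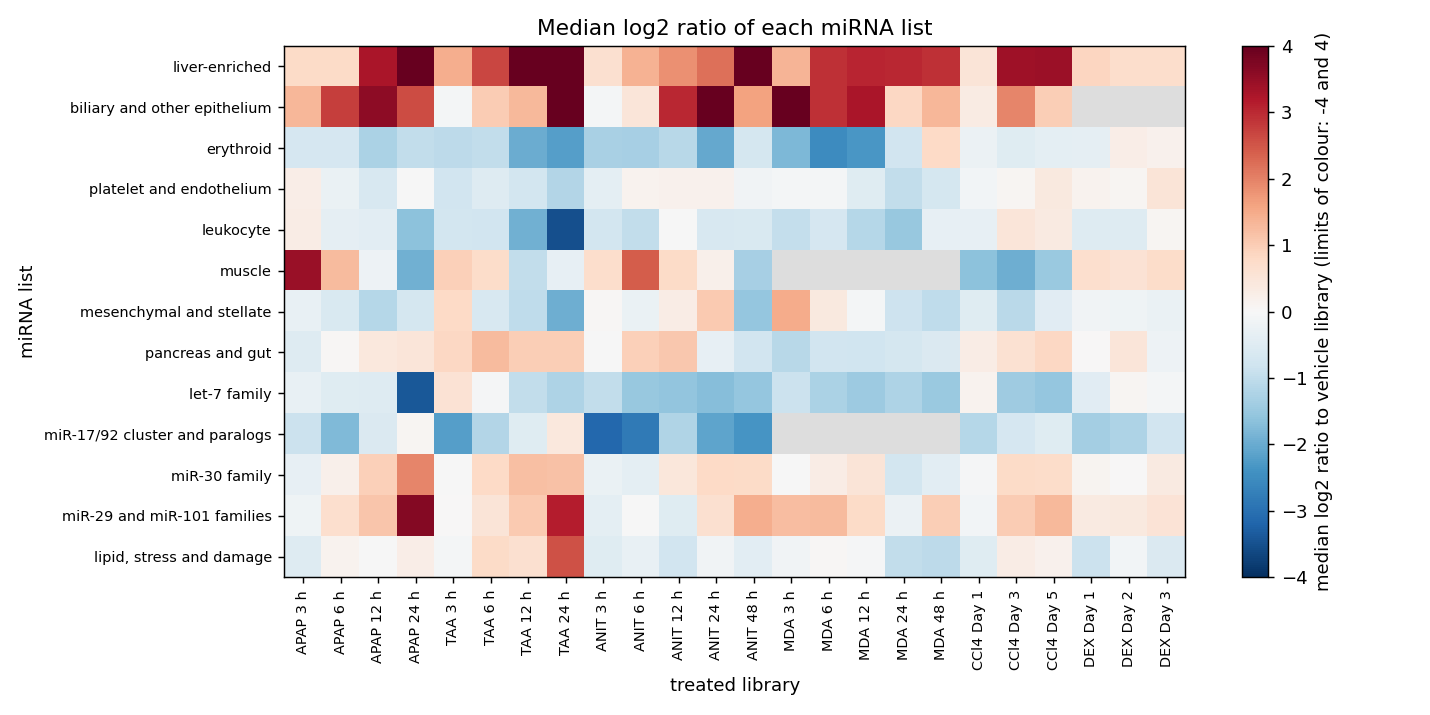
Median log2 ratio to the vehicle library for each miRNA list (vertical axis) in each treated library (horizontal axis), with TMM scaling, colours limited to −4 and 4, and grey where fewer than 3 members were measured. The liver-enriched list has medians of 4.52 in APAP and 4.55 in TAA at 24 h, and total counts lower them to 2.99 and 2.73. It had 9 measured members in APAP and 8 in TAA, but 4 in ANIT and MDA and 5 in CCl4 and DEX. Its medians are therefore not over the same miRNAs in all models.

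Across the other lists, percentiles of the platelet and endothelial list ran from 2.5 (TAA 3 h) to 80.4 (DEX Day 3), of the pancreas and gut list from 7.4 (APAP 3 h) to 93.0 (ANIT 12 h), of the miR-30 family from 10.2 (APAP 3 h) to 93.6 (APAP 24 h), and of the lipid, stress and damage list from 3.6 (CCl4 Day 1) to 88.9 (TAA 24 h). The miR-29 and miR-101 families were at 97.9 in APAP at 24 h, where 3 of 3 members were higher with a median of 3.68 (2.15 with total counts). For the brain list 1 member was measured, miR-128-3p, and no member of the Dlk1-Dio3 cluster reached the read minimum in any model.

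Vehicle libraries also differed from each other. Between pairs of the 5 vehicle libraries, 3.97% to 28.6% of the measured miRNAs passed the rule of size (median 9.52%), and the 4 pairs with the TAA vehicle gave 18.3% to 28.6%. In the treated libraries 15.2% to 79.7% passed (median 40.7%), so the lowest values of treated libraries lie inside the range between vehicles. Against each of the 5 vehicle libraries, 40 miRNAs were higher and 31 lower in APAP at 24 h, 46 and 35 in TAA at 24 h, 1 and 1 in ANIT at 3 h, and 1 and 1 in CCl4 at Day 1. miRNAs chosen after their values were seen were, out of 24 treated libraries, higher than the own vehicle in 23 for miR-192-5p, in 19 for miR-182 and miR-30a-3p, in 18 for miR-183-5p and miR-3559-3p and in 17 for miR-200a-3p and miR-375-3p. Lower in at least 15 libraries were miR-16-5p (22), miR-150-5p (20), miR-93-5p (16 of the 19 where it was measured), and let-7a-5p, let-7d-5p and miR-451-5p (15 each). Against each of the 5 vehicles the counts were 17 for miR-192-5p, miR-182, miR-30a-3p, miR-183-5p and miR-16-5p, 16 for miR-3559-3p, 14 for miR-200a-3p, 13 for miR-93-5p and miR-451-5p, 11 for miR-150-5p, 10 for miR-375-3p and let-7a-5p, and 5 for let-7d-5p.

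With the 6 models as replicates, miR-122-5p rose at 24 h or Day 1 by a log2 change of 4.81 (SE 0.60, adjusted p 0.000414), a 28.1-fold change. miR-192-5p rose by 3.89 (SE 0.87, adjusted p 0.0394), miR-182 by 2.32 (SE 0.59, adjusted p 0.04996) and miR-3559-3p by 2.53 (SE 0.65, adjusted p 0.04996). miR-93-5p changed by −2.37 (SE 0.54, adjusted p 0.0394) and miR-16-5p, found in red cells and many other cells, by −1.91 (SE 0.50, adjusted p 0.04996). Each of these 6 miRNAs moved in its direction in 6 of 6 models, by edgeR with Benjamini-Hochberg adjustment over 134 miRNAs, and 42 miRNAs had an unadjusted p under 0.05. With total counts 2 were higher and 30 lower, with 4 of the 6 calls shared. Of 5 liver-enriched miRNAs 2 passed over all tested and 3 adjusted over the list alone. Adjusted over the list alone, the other lists gave 2 higher of 3 epithelial (over all tested with total counts 0 higher and 1 lower), 2 lower of 6 erythroid, 1 lower of 8 leukocyte, 1 higher and 1 lower of 3 muscle, 2 lower of 4 miR-17/92 and 2 higher of 7 miR-30 miRNAs. Over all tested with total counts, 4 erythroid, 4 leukocyte, 5 let-7 and 2 miR-17/92 miRNAs were lower. Of the 6 calls 3 lie just under the threshold, and leaving out APAP, ANIT or MDA left 1 call, TAA 3, CCl4 10 and DEX 11.

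In the hepatocellular models (APAP and TAA at 24 h) miR-101b-3p rose by 7.13 on the log2 scale (SE 0.97, adjusted p 8.92e-11), miR-192-5p by 6.26 (SE 0.95, adjusted p 5.84e-09), miR-22-3p by 5.78 (SE 0.93) and miR-194-5p by 5.27 (SE 0.86). miR-3559-5p had the smallest p (7.68, SE 1.02, adjusted p 5.41e-11). miR-122-5p rose by 4.68 (SE 0.90, adjusted p 3.71e-06) and miR-200a-3p by 4.68 (SE 0.84). The lymphocyte miRNA miR-150-5p changed by −5.25 (SE 0.85, adjusted p 5.28e-08), the muscle miRNAs miR-206-3p by −5.06 (SE 0.93) and miR-1-3p by −3.73 (SE 0.81), and miR-199a-3p by −3.58 (SE 0.78). By edgeR 36 miRNAs were higher and 43 lower, each called one with the same sign in both models, and with total counts 12 were higher and 73 lower, as that scaling moved the median log2 change of the tested miRNAs from −0.47 to −2.30. By list, 4 of 5 liver-enriched miRNAs (3 with total counts), 3 of 3 of miR-29 and miR-101 (1 with total counts) and 2 of 3 epithelial miRNAs (2 with total counts) were higher. Of the miR-30 family 4 of 7 were higher, but with total counts 1, and the family's median went from 1.65 to −0.18. Of the leukocyte list 4 of 8 were lower (miR-223-3p, miR-150-5p, miR-146b-5p and miR-181a-5p), of let-7 5 of 8, of the mesenchymal list 4 of 8 with 2 higher (6 lower and 0 higher with total counts), and of the erythroid list 2 of 6 (miR-486 and miR-363-3p). With total counts the lower ones were 8 of 8 leukocyte, 7 of 8 let-7 and 6 of 6 erythroid. Of the muscle list 2 of 3 were lower and miR-378a-3p was higher (4.39, adjusted p 4.74e-06). The brain miRNA miR-128-3p was lower too, and of the pancreas and gut list 1 of 3 (miR-215). Adjusted over the list alone, the counts were 4 liver-enriched, 4 leukocyte, 5 let-7 and 2 erythroid, with 1 further epithelial miRNA lower. Without TAA 48 miRNAs passed, 45 of them shared with the full fit. With the TAA vehicle library left out and TAA set against the APAP vehicle 48 passed, all 48 shared with it.

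In the cholestasis models (ANIT and MDA at 24 h) miR-122-5p rose by 5.79 (SE 0.94, adjusted p 2.75e-07) and the epithelial miRNAs miR-200a-3p by 4.78 (SE 1.01, adjusted p 0.000205) and miR-200b-3p by 3.77 (SE 1.05, adjusted p 0.00822). The joint log2 ratios of miR-200a-3p and miR-200b-3p were 6.06 and 4.26 in ANIT but 2.10 and 1.00 in MDA, and within MDA neither passed the rule at 24 h. miR-192-5p rose by 3.75 (SE 0.87), miR-182 by 2.55 (SE 0.76) and miR-194-5p by 2.42 (SE 0.82, adjusted p 0.0321). miR-93-5p changed by −3.06 (SE 0.82, adjusted p 0.00611), miR-16-5p by −2.75 (SE 0.78) and miR-98-5p by −4.22 (SE 1.02), the last with 0 reads in ANIT at 24 h, so that its fitted value depends on the prior count. By edgeR 11 miRNAs were higher and 4 lower, each with the same sign in both models, and with total counts 3 and 27, with the median of the tested miRNAs moved from 0.10 to −1.19. The list counts were 3 of 5 liver-enriched and 2 of 3 epithelial higher (3 and 2 adjusted over the list alone, 2 and 1 with total counts), 1 of 6 erythroid lower, 1 of 4 miR-17/92 lower (3 adjusted over the list alone), 1 of 8 let-7 lower and 0 of 8 leukocyte. With total counts 4 erythroid, 3 miR-17/92, 6 let-7 and 4 leukocyte miRNAs were lower. Leaving out ANIT gave 4 calls, MDA 6, CCl4 2 and DEX 8, and the fit with TAA set against the APAP vehicle 6.

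In the steatosis models (CCl4 and DEX at Day 1) no miRNA passed by edgeR after Benjamini-Hochberg adjustment, 0 of 134, with 4 at an unadjusted p under 0.05. DESeq2 called 1. The smallest p belonged to miR-122-5p, whose log2 change was 3.71 (SE 1.15, adjusted p 0.174), higher in both models, and it passed adjusted over the liver-enriched list alone, 1 of 5, and by DESeq2 (adjusted p 2.59e-09). The muscle miRNA miR-1b (−2.09, SE 0.79, adjusted p 0.572) and miR-93-5p (−1.81, SE 0.81, adjusted p 0.965) came next and did not pass. Leaving out MDA or CCl4 gave 1 call. Both steatosis models share 1 vehicle library.

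Between types, the hepatocellular change exceeded the cholestasis change for miR-3559-5p by 6.57 (SE 1.37, adjusted p 0.000283), for miR-101b-3p by 4.40 (SE 1.16, adjusted p 0.00639) and for miR-30b-5p by 3.97 (SE 1.09, adjusted p 0.00736). It was lower for miR-676 (−7.63, SE 1.84, adjusted p 0.00273), miR-140-5p (−4.77, SE 1.27), miR-218a-5p (−4.31, SE 1.20), let-7b-5p (−3.68) and miR-150-5p (−3.48). By edgeR 8 miRNAs were more positive and 18 more negative in the hepatocellular models. With total counts 3 and 19 passed. miR-676 had 0 reads in APAP and TAA at 24 h and 5 in each vehicle library, and miR-140-5p 0 in TAA at 24 h, so the sizes fitted for them depend on the prior count. The size for miR-3559-5p, here and against steatosis, rests on a few reads in the APAP and TAA vehicle libraries. Of liver-enriched miRNAs 1 of 5 passed as more positive (3 adjusted over the list alone), and of the miR-29 and miR-101 families 1 of 3 (3 adjusted over the list alone). So did 1 of 4 miR-17/92, 1 of 7 miR-30 and 1 of 5 lipid, stress and damage miRNAs. More negative were 2 of 8 leukocyte, 2 of 8 mesenchymal, 1 of 3 muscle, 1 of 8 let-7 and 1 of 3 pancreas and gut miRNAs. At the last sampling time 4 passed. Leaving out CCl4, a model outside this contrast, gave 0 calls, with little change in size for miR-3559-5p (6.47, SE 1.27, adjusted p 0.0946) and miR-101b-3p (4.30, SE 1.13, adjusted p 0.152), while the degrees of freedom of the test went from 402 to 6.86. Leaving out TAA gave 4, ANIT 10, MDA 14, DEX 12 and APAP 41, and setting TAA against the APAP vehicle, with the TAA vehicle left out, gave 1.

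Against steatosis, the hepatocellular change was more positive for miR-101b-3p by 7.21 (SE 1.22, adjusted p 1.11e-06), miR-3559-5p by 6.72 (SE 1.34), miR-30b-5p by 5.20 (SE 1.13), miR-22-3p by 5.20, miR-192-5p by 4.98 (SE 1.19, adjusted p 0.000816) and miR-200a-3p by 4.09. More negative were miR-676 (−8.21, SE 1.90), miR-206-3p (−5.36, SE 1.31, adjusted p 0.00101), miR-181b-5p (−4.96, SE 1.26), let-7b-5p (−4.47) and miR-150-5p (−4.20). By edgeR 22 miRNAs were more positive and 31 more negative, and with total counts 5 and 45. By list 3 of 5 liver-enriched and 2 of 3 epithelial miRNAs passed as more positive (1 and 0 with total counts), and 4 of 8 leukocyte and 4 of 8 let-7 miRNAs as more negative (5 for let-7 adjusted over the list alone). At the last sampling time 0 passed. Without CCl4 0 passed, where miR-101b-3p had 7.02 (SE 1.46, adjusted p 0.063) and miR-192-5p 4.84 (SE 0.96, adjusted p 0.063), without TAA 27, without DEX 16, and with TAA set against the APAP vehicle 13. For cholestasis minus steatosis edgeR called 0 miRNAs, with 6 at an unadjusted p under 0.05, and DESeq2 0 with 12. The smallest p was that of miR-200a-3p (4.19, SE 1.31, adjusted p 0.196), followed by miR-200b-3p (3.48, SE 1.39, adjusted p 0.56) and miR-98-5p (−3.31, SE 1.32, adjusted p 0.56). Adjusted over the list alone, 2 of 3 epithelial miRNAs passed there, and leaving out MDA gave 2 calls, APAP 1 and TAA 1.

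**Figure D3:**
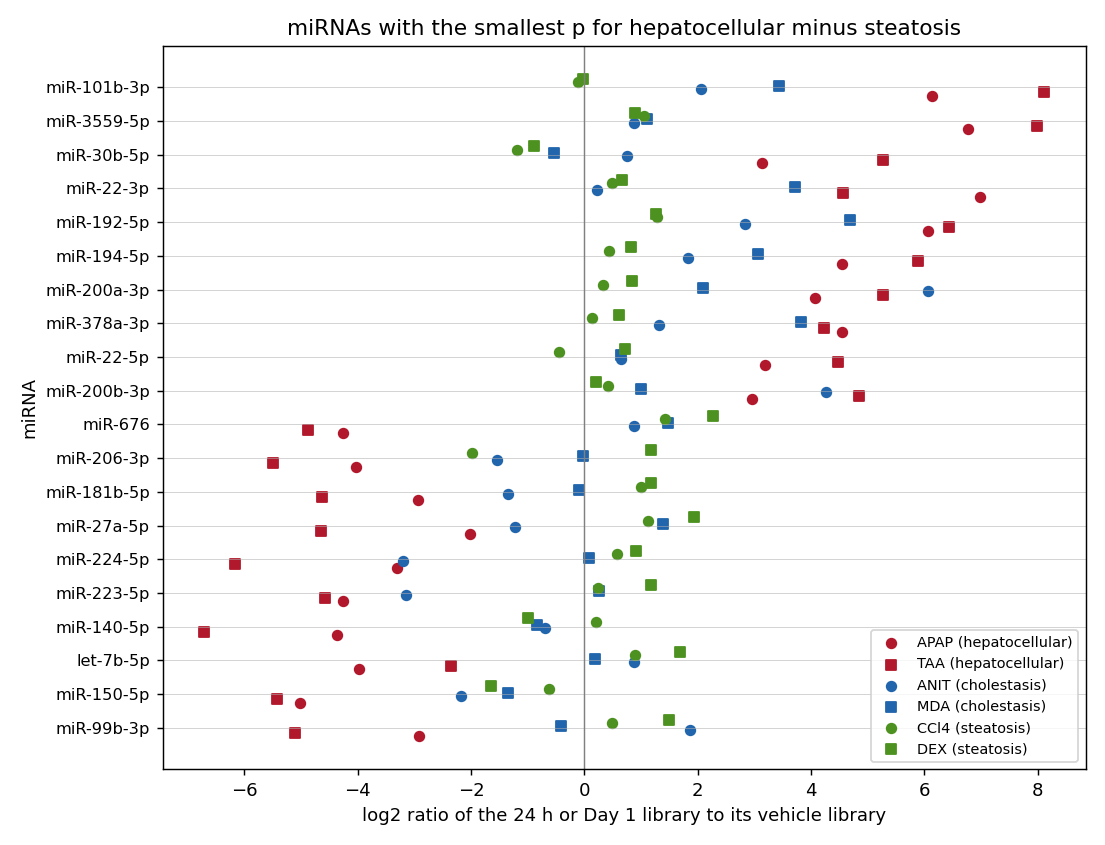
Log2 ratio of the 24 h or Day 1 library to its vehicle library (horizontal axis) in each of the 6 models for the miRNAs with the smallest p for hepatocellular minus steatosis, 10 per direction, 1 point per model coloured by injury type. The fitted difference is 7.21 for miR-101b-3p and −8.21 for miR-676. The points of miR-676 are −4.26 in APAP and −4.87 in TAA, against 1.43 in CCl4 and 2.27 in DEX. miR-676 had no reads in APAP and TAA at 24 h, and miR-224-5p, miR-223-5p, miR-140-5p and miR-99b-3p had none in TAA at 24 h. These points rest on the pseudocount, and the differences fitted for these miRNAs depend on the prior count.

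Profiles at 24 h or Day 1 were compared by the correlation of log2 ratios across 134 miRNAs, which are not independent replicates. APAP and TAA had r = 0.84 (rho 0.83, and r 0.84 with total counts), the highest of the 15 pairs of models. CCl4 and DEX had r = 0.66, but their shared vehicle alone gave a simulated r of 0.47, and their covariance of 0.53 was close to the simulated 0.49. ANIT and MDA had r = 0.49, less than MDA with DEX (0.59) or APAP with either of them (0.57 each). The lowest value was TAA with DEX (0.01).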

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

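The tests of red cell RNA and of scaling for miR-16-5p, the count of other splits, and the fit without the TAA vehicle library were chosen after the results they concern were seen.

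The hepatocellular models differed from both other injury types at 24 h by a test of the difference itself (edgeR, Benjamini-Hochberg adjusted). Against cholestasis 26 miRNAs passed, with log2 differences of 6.57 for miR-3559-5p, 4.40 for miR-101b-3p, 3.97 for miR-30b-5p, −7.63 for miR-676, −4.77 for miR-140-5p and −4.31 for miR-218a-5p among the smallest p. Against steatosis 53 passed, with 7.21 for miR-101b-3p, 6.72 for miR-3559-5p, 5.20 for miR-30b-5p, −8.21 for miR-676, −5.36 for miR-206-3p and −4.96 for miR-181b-5p. In the hepatocellular models miR-676 had 0 reads at 24 h, so its size depends on the prior count. The sizes for miR-3559-5p rest on a few reads in the APAP and TAA vehicle libraries. The numbers of calls did not hold, with 4 and 0 at the last sampling time and 0 and 0 without CCl4, where the degrees of freedom of the test went from 402 to 16.8 and 6.86.

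For the sizes of these differences, library depth was not decided. With each library thinned to 14176 reads in 20 draws, a median of 12.5 of 26 and 28 of 53 called differences could still be tested. These had 103% of their full median size against cholestasis and 107% against steatosis, though 5 and 11 miRNAs passed. Random thinning keeps the expected share of each miRNA, so kept sizes could be foreseen, and miRNAs with too few reads left the test. A few abundant miRNAs acting through 1 shift were argued against as the only source of the sizes in APAP and TAA. Outside the 10 most abundant miRNAs the interquartile range of log2 ratios was 3.73 in APAP and 5.20 in TAA. Between pairs of vehicle libraries it was at most 1.30. It was 2.11 in ANIT, 1.92 in MDA, 1.69 in DEX and 0.97 in CCl4. A shift leaves this range unchanged, so a part of a shift in the differences between types was not tested. Total counts moved the median log2 difference of the tested miRNAs from −0.14 to −1.89 against steatosis and from −0.28 to −0.84 against cholestasis. The TAA vehicle library was not the source of the signs of the TAA 24 h ratios. At least 98.2% of the called miRNAs kept that sign against each other vehicle library. These miRNAs were called for large differences, which makes kept signs likely, and the count does not cover the difference between types. A further fit left the TAA vehicle library out and set TAA at 24 h against the APAP vehicle, so that both models share 1 vehicle. There all 26 and 52 called differences that could be tested kept their sign. Their median size went from 3.68 to 3.35 and from 3.62 to 3.64, and the median SE from 1.149 to 1.246 and from 1.206 to 1.279. Only 1 and 13 miRNAs passed, but the degrees of freedom of the test also went from 402 to 13.5. Whether the calls rest on the TAA vehicle library therefore stays open. A biological difference by injury type stays open and untested, because each type is 2 compounds. Vehicle fluid differs too, with corn oil in ANIT, CCl4 and DEX, and CCl4 and DEX were given once daily. Sampling time was not told apart either. At the last sampling time APAP and TAA kept their 24 h libraries, while the other models moved to later ones. In CCl4 the log2 ratio of miR-101b-3p went from −0.12 at Day 1 to 3.39 at Day 5, and that of miR-192-5p from 1.30 to 4.27. In DEX the share of miR-192-5p was 2.175% at Day 1 and 2.222% at Day 3.

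With total counts, lower calls outnumbered higher ones in most treated libraries. Over the 14 treated libraries whose log2 shift between both scalings is above 0.5, the median shift of 1.39 became −0.07 once the 3 most abundant miRNAs of each treated library were left out of the totals, so −5.05% of it was left. In the 24 h libraries of the hepatocellular models more was left, 0.54 of 1.53 in APAP and 0.59 of 1.82 in TAA. The median fits a few abundant miRNAs taking the reads of the others. miR-122-5p was the most abundant of the 3 in most of these libraries. In APAP at 24 h and CCl4 at Day 3 and Day 5 it was miR-148a-3p, and in TAA at 24 h miR-192-5p. No biological explanation was tested, and without a spike-in a real loss of the other miRNAs stays open.

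miR-16-5p and miR-93-5p were lower at 24 h or Day 1 in all 6 models. Less red cell RNA in treated plasma stays open, because neither prediction set for it was met. Against it, the log2 ratios of the red cell miRNAs miR-451-5p and miR-486 were both to exceed that of miR-16-5p in several models. The excess had to pass the range of these differences over the vehicle libraries (1.43 and 1.78), and did so in 1 of the 6 models, MDA. For red cell loss, both were to fall at least as much as miR-16-5p in nearly all models. Both did so in TAA, and miR-486 alone in APAP, while in the other models both fell less. Against counting error alone, the criterion first used, both lay above the interval of miR-16-5p in 4 models, but that leaves out differences between libraries, and the ratios of miR-451-5p and miR-486 were 0.261 and 0.223 in ANIT, 0.301 and 0.589 in MDA, 0.704 and 0.892 in CCl4, 0.718 and 0.955 in DEX, 0.509 and 0.154 in APAP and 0.218 and 0.0371 in TAA. Total counts, with a highest ratio of miR-16-5p of 0.393, lower each ratio by construction and so could not test scaling. With 1 TMM over all libraries, miR-16-5p was lower than each of the 5 vehicle libraries in 17 of 24 treated libraries and miR-93-5p in 13 of 19. By DESeq2 across 6 models both passed (adjusted p 0.00026 and 2.1e-05), but DESeq2 changes the test too and called 48 miRNAs. With DESeq2's size factors alone changed in edgeR, 4 higher and 1 lower miRNA passed. There 1 of miR-16-5p and miR-93-5p thus lost its call. Neither miRNA turned its direction in the joint fit under the scalings run, but without a spike-in scaling stays open as well. A lower supply of these miRNAs from other blood cells was not tested.

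For the 6 miRNAs called across 6 models, 3 of 48 splits within the vehicle sets gave at least as many, the real one included, and the highest other split gave 18. Chance could therefore not be excluded by this count. Both other splits exchange vehicle and treated library in the 4 sets of 1 pair and put CCl4 or DEX in place of the shared vehicle. That makes them close to the real contrast with its sign turned. The split that exchanges the 4 pairs alone gave 0, as did every further split. Whether this closeness explains the calls of both splits was not tested.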

How the results depend on the processing

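The alternatives with the TAA vehicle library left out (TAA at 24 h then set against the APAP vehicle), with the DEX table's vehicle counts, with 1 TMM over all libraries, and against each of the 5 vehicle libraries were chosen after the data were seen. No paired analysis was possible because the labels give no animal numbers that link libraries. The ANIT tests with 2 libraries per group, their leave-one-out, replicate block and 4-library fits, ANIT counts summed over libraries, and the tests of lists within ANIT were planned and not run, since the table has 1 column per group.

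No single miRNA named from the joint fits reversed its direction under the alternatives run. With total counts, which lower all ratios of a library alike, medians of several lists turned negative, such as the miR-30 family from 1.65 to −0.18 in the hepatocellular and 0.67 to −0.65 in the cholestasis models, and 5 calls in APAP at 12 h and 4 in TAA at 12 h were opposite. Of 84 named joint results, 82 kept direction and side of the threshold with DESeq2's size factors, 82 with DESeq2, 78 with no filter, 81 with the DEX table's vehicle and 64 with total counts. At the last time 41 of 73 did, and without the TAA vehicle 44 of 82. With 1 model left out 345 of 492 did, 141 no longer passed and 6 newly passed. Sums of higher and lower calls by the rule of size stayed within 1.5 times in 24 of 24 libraries with the authors' normalized signal, with a minimum of 50 reads and with 1 TMM over all libraries, but their balance did not. The share of higher calls moved by over 10 points with the authors' signal in APAP at 12 h (29 higher and 17 lower), TAA at 3 h (21 and 8) and 12 h (39 and 31), ANIT at 3 h (15 and 13), and MDA at 3 h (23 and 18), 6 h (22 and 20), 24 h (25 and 18) and 48 h (31 and 16), and with the minimum of 50 reads in APAP at 6 h (20 and 7) and TAA at 3 h (14 and 8) and 6 h (19 and 5). With 1 TMM over all libraries it moved as much in every MDA, CCl4 and DEX library (19 and 32 in DEX at Day 3) and at 3 h in APAP (12 and 17), TAA (10 and 17) and ANIT (11 and 14). The ratio of miR-122-5p moved beyond its counting interval in 21 of 24 libraries with total counts in 14 of 24 with the authors' signal, and in 20 of 24 with 1 TMM over all libraries. With total counts the similarity of APAP and TAA stayed at 0.84.

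Counts of called miRNAs that moved were as follows, and the cause was not tested except where stated. Across 6 models (6 calls) there were 32 with total counts, 35 with no filter, 48 with DESeq2, 31 at the last time, 3 with the DEX table's vehicle, 2 without the TAA vehicle, and 1 to 11 with a model left out. For hepatocellular (79) there were 48 without the TAA vehicle and 48 to 79 with a model left out. For cholestasis (15) there were 30 with total counts, 28 with DESeq2, 6 without the TAA vehicle, and 2 to 18 with a model left out. For steatosis (0) there was 1 with DESeq2's size factors, 1 with total counts, 1 with DESeq2, and 0 to 1 with a model left out. For hepatocellular minus cholestasis (26) there were 40 with DESeq2, 4 at the last time, 1 without the TAA vehicle, and 0 to 41 with a model left out. For hepatocellular minus steatosis (53) there were 0 at the last time, 13 without the TAA vehicle, and 0 to 52 with a model left out. For cholestasis minus steatosis (0) a model left out gave 0 to 2.

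With total counts, calls by the rule of size numbered 72 in APAP at 6 h and 98 at 12 h, 57 in TAA at 3 h and 76 at 6 h, 87 in ANIT at 48 h, and 92 in CCl4 at Day 3 and 90 at Day 5, where the alternative lowers every ratio of a library by 1 factor. Against each of the 5 vehicles both the needed agreement of 5 comparisons and the scaling differ, and calls numbered 7, 13 and 26 in APAP at 3, 6 and 12 h, 9, 16 and 37 in TAA at 3, 6 and 12 h, 2, 9, 17, 28 and 28 in ANIT in order of time, 25, 26, 22 and 26 in MDA at 3, 6, 24 and 48 h, 2, 19 and 15 in CCl4, and 9, 10 and 17 in DEX.

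Depth limits the shallow libraries most, with 14176 reads in the MDA vehicle, where a miRNA under 0.0212% of reads cannot be told from absent.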

Other observations

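The muscle and let-7 values were picked out after they were seen, and neither test of pairs was.

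Muscle miRNAs stood apart early in some models. In APAP at 3 h the muscle list had a median log2 ratio of 3.46 (3.22 with members at 0 reads at the floor, 3.27 with total counts) at percentile 100.0 of random lists, with 3 of 4 members higher, among them miR-133a-3p, at least 8.94-fold higher from 0 reads in vehicle. In ANIT at 6 h the median was 2.41 (1.92 with total counts) at percentile 99.8, where miR-1-3p was 8.30-fold higher (95% counting interval 6.20 to 11.3) and miR-206-3p 5.42-fold. These are single libraries, and neither muscle injury nor handling is recorded in the sources used here.

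The let-7 family split in ANIT. In the 6 h library let-7b-5p was 3.95-fold higher (3.25 to 4.82) and let-7c-5p 4.53-fold higher (4.02 to 5.13), both higher with total counts too, while let-7a-5p was 2.35-fold lower, let-7f-5p 3.51-fold lower and miR-98-5p 21.6-fold lower. Against each of the 5 vehicle libraries, let-7c-5p was higher and let-7f-5p lower in 0 of 24 treated libraries of all models. let-7b-5p was higher in 4 of 24, let-7a-5p lower in 10 of 24 and miR-98-5p lower in 4 of 15. The list's percentile was 0.0 there, with 2 of 8 members higher and 6 lower. In DEX at Day 1 let-7b-5p was 3.31-fold higher (2.98 to 3.69) and let-7c-5p 3.30-fold. In APAP at 24 h let-7b-5p was 16.4-fold lower (9.76 to 29.4) and 7 of 8 members were lower, with a median of −3.38. Members of this family differ by few bases, and reads passing between them in counting were not tested.

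miRNAs cut from the same hairpin may move together. Over the 6 models, log2 ratios at 24 h or Day 1 of both arms differed by a median of 1.35 in 17 pairs, against 1.86 for randomly paired arms (one-sided permutation test with 100000 permutations, p 0.00363, adjusted over both pair tests 0.00363). Both arms of miR-22, miR-30a and miR-3559 were among the pairs.

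miRNAs whose genes lie next to each other may also move together. For genes within 10 kb, found by name in the rat annotation for 117 of the 134 miRNAs, 21 pairs of 25 miRNAs differed by a median of 0.86, against 1.76 for random pairs (one-sided permutation test, p 3e-05, adjusted 6e-05). Among these pairs are miR-182 with miR-183-5p, miR-200a-3p with miR-200b-3p, and miR-143-3p with miR-145-5p. Some pairs share a member, and the more alike sequences of a cluster may share reads, so transcription as 1 unit was not told apart from reads shared in counting.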
